A study of Homo sapiens with 4 samples.

How the data were processed

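RNA was measured in TE5 cells, an established line from an esophageal squamous cell carcinoma, in 4 libraries: 2 from cells with a control short hairpin RNA (shControl) and 2 from cells with hairpin RNA against NUP153 (shNUP153). Per the labels' protocols, hairpins were delivered by lentivirus, infected cells were selected with puromycin and grown for 7 more days, and total RNA was column-purified and sent to a sequencing company. The labels give each library a group and a replicate number. They do not say that replicates came from separate infections or cultures, so p-values measure only the spread between these samples, which may be technical. The descriptions of the shNUP153 libraries end in g1 and g2, those of the shControl libraries in a number alone. Whether g1 and g2 mark different hairpins is not given in the sources used here, and if they do, the spread between the shNUP153 libraries includes the difference between hairpins.

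The deposited table lists Ensembl gene IDs by row, each with a symbol, and holds 1 column of counts per library. Its name says FPKM, yet the deposited values are whole numbers that sum to a different total in each library, so they were treated as raw read counts, as the authors left them, with no normalization. The submitters' processing notes list kallisto, DESeq2, Bowtie2 and deepTools and the genome build hg19, with no role or version given. Which tool made the counts, the gene annotation used and whether counting used strand are not given in the sources used here. Without a stated strand, reads from genes that overlap on opposite strands cannot be told apart, and reads shared by near-identical genes could have been split or dropped by the counting. Members of close families (keratins, SPRR2, AKR1C, CEACAM, histone, IFIT and ribosomal protein genes) are uncertain in this respect.

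The authors' deposited table also holds a log2 ratio and a p-value per gene. The log2 ratio was recomputed as the mean of the shNUP153 counts plus 0.005 over the mean of the shControl counts plus 0.005, to within 4.3e-09, so it carries no correction for library size. The deposited p-values were recomputed to within 5e-10 as a one-sided paired test of libraries with the same number. Neither column entered the tests described here.

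The test plan was fixed before the data were examined. It named limma on log2(FPKM + 1) for an FPKM table and edgeR for a table of counts, so the second was used, the lists being tested on the same count fit, and the levels given are CPM (counts scaled to library size) with TMM scaling rather than FPKM. Of 56657 rows, 24486 were at 0 in all libraries and 45 gene IDs were listed more than once, with a count in 1 of those rows. No row lacked a gene name. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 16817 genes. Differences were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test at its default settings, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The standard error of a log2 fold change was derived from the fold change and its F statistic. With 2 libraries per group, 2 residual degrees of freedom remain per gene and the spread is pooled across genes.

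The 34 gene lists were written before the data were examined and tested with camera in limma 3.58.1, a competitive test with the correlation between genes preset at 0.01, on lists with 5 or more measured genes. The estimated correlation and the self-contained test fry were alternatives. With the estimated correlation camera has only the 2 residual degrees of freedom, so few lists could pass it whatever their correlation. For each list, members past the test of all genes were counted, as were those past it when p was adjusted over the list alone. Genes to be named were fixed by rule: NUP153; the 10 largest rises and the 10 largest falls among genes past the threshold whose libraries do not overlap between groups and whose mean reaches 5 CPM in the higher group; up to 4 members of each list with the smallest p; and TP63, SOX2, KLF5, KRT5, NUP50, NUP98 and TPR. Other members named to fill out a count of 5 or fewer, and further genes in the closing section, were chosen after their values were seen. Some genes that these rules name are not reported here. Also chosen after their values were seen were CXCL10, CXCL11, MMP9, HMOX1, FOS, OCLN and RSAD2.

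Replicates were compared first. Over genes with 20 or more counts, the chi-square per gene was 3.57 between the shControl libraries and 3.09 between the shNUP153 libraries. Sampling noise alone gives about 1, so replicates differed by more than sampling noise. The source of the excess was not tested. It does not show whether replicates share a library, a culture or an RNA sample. The test procedure was checked on simulated counts for these 16817 genes. It recovered 28% of genes changed 1.2-fold, 68% at 1.5-fold, 80% at 2-fold and 94% at 4-fold, and called 9 of 16617 unchanged genes. A changed list was called and 0 of 40 unchanged lists were. Genes were drawn independently and 200 of them were changed. The list result therefore cannot check the preset correlation. In the data the estimated correlation was 0.627 for the type I interferon list and 0.726 for mitochondrially encoded transcripts. Recovery was not simulated with as many changed genes as the 32.4% called here. Intervals and errors cover these libraries only.

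Alternatives covered the pseudocount (0.1 and 5, with limma on log2 CPM), no filter, a mean of 5 CPM or more, quantile and median-of-ratios scaling, no variance trend, robust variance, a replicate block, leaving out each library, DESeq2 1.42.0 and a threshold on fold change. Added after seeing the data were limma on log2(CPM + 1), total-count scaling, offsets for GC content and exonic length, and edgeR's bias-adjusted quasi-likelihood method. The choice of edgeR's default over that method was settled after both counts of changed genes had been seen (5448 and 5504). Gene types, lengths, GC content and overlaps on opposite strands came from GENCODE release 29, matched by gene ID for all 56657 rows. That release uses another genome build than the one listed by the submitters, so no coordinates are given.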

Results

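Gene expression was profiled by RNA sequencing in TE5 cells, an esophageal squamous cell carcinoma line, carrying a control hairpin (shControl, n = 2 libraries) or hairpin RNA against NUP153 (shNUP153, n = 2). Whether both shNUP153 libraries carry the same hairpin is not given in the sources used here. Effects of hairpin RNA on other genes cannot be told apart here from effects of NUP153 loss. The comparison asks how depletion of NUP153, a nucleoporin of the nuclear basket, changes gene expression in these cells at day 7. The shControl libraries held 22606593 and 27396268 counts and the shNUP153 libraries 25247932 and 23396626. Between 25494 and 26965 genes had at least 1 count in a library. Across genes, which are not independent replicates, log2 CPM correlated at Pearson r = 0.9974 within shControl, 0.9977 within shNUP153 and 0.992 to 0.9921 between groups.

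NUP153 (ENSG00000124789), the target, fell 1.94-fold. It measured 148.9 and 141.6 CPM in the shControl libraries and 67.9 and 81.9 CPM in the shNUP153 libraries (145 ± 5.17 against 74.9 ± 9.90, SD, n = 2 each), a log2 fold change of −0.96 (SE 0.06, edgeR adjusted p = 1.051e-14). The authors' deposited table gives a log2 ratio of −0.93 for it. NUP153 overlaps AL138724.1 on the opposite strand by 558 bp, and that gene measured 5.32 CPM in shControl and 4.83 in shNUP153. With NUP153 reduced, interferon-stimulated genes such as OASL and IFIT1 and DNA replication genes such as GINS1 and RRM2 fell, while the stress cytokine GDF15, the cell cycle inhibitor CDKN1A, immediate early genes such as FOSB and the cornified envelope precursor IVL rose.

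By edgeR's quasi-likelihood test, 5448 of 16817 tested genes changed at an adjusted p under 0.05 (32.4%), 2521 higher and 2927 lower in shNUP153. With total-count scaling the split was 3573 higher and 2114 lower, 62.8% of calls higher against 46.3% with TMM. Most changes were small. At least 2-fold differences were found for 376 higher and 147 lower genes. The libraries of the groups did not overlap for 64.4% of tested genes, where chance gives 33.3%. The count was 3027 genes without shNUP153 replicate 1 and 3300 without shNUP153 replicate 2, and DESeq2 called 3556. It was 2704 with limma without a variance trend.

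**Figure D1:**
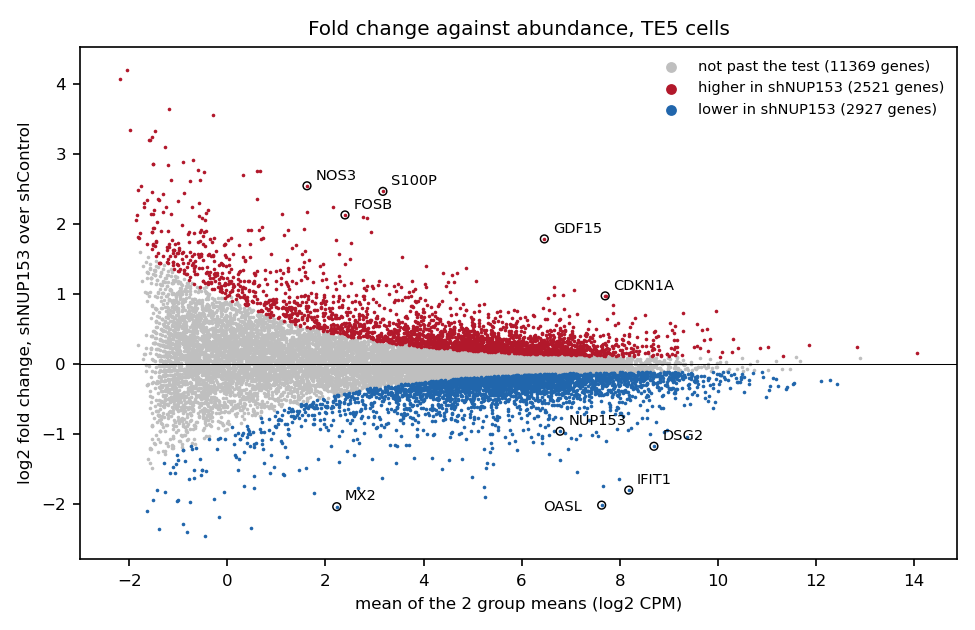
Log2 fold change of shNUP153 over shControl against mean abundance (log2 CPM, mean of the 2 group means), 1 point per tested gene, with genes past edgeR's test in red (2521 higher) and blue (2927 lower). NUP153 lies at −0.96, and the interferon-stimulated genes OASL and MX2 at −2.01 and −2.03.

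The 10 largest rises among genes reaching 5 CPM were led by NOS3, endothelial nitric oxide synthase, at 0.893 ± 0.116 against 5.27 ± 0.00981 CPM (SD, n = 2), 5.83-fold. NOS3 overlaps ATG9B on the opposite strand by 786 bp, and ATG9B also rose (log2 fold change 1.70), so reads of this pair cannot be separated. The calcium-binding protein gene S100P rose 5.52-fold, from 2.76 ± 0.0766 to 15.3 ± 1.204 CPM. CAPN8 rose 4.71-fold, PHF21B 4.48-fold, FOSB 4.37-fold, the cell surface glycoprotein gene CEACAM5 4.28-fold, the chemokine gene CCL20 4.26-fold, LINC02154 3.40-fold and ANXA10 3.33-fold. GDF15 was the most abundant of the 10, at 39.5 ± 5.91 CPM in shControl and 137 ± 3.32 in shNUP153 (3.45-fold, adjusted p = 3.41e-21).

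The 10 largest falls included the interferon-stimulated genes MX2 (4.09-fold lower), OASL (4.03-fold), CMPK2 (3.70-fold), IFIT1 (3.47-fold), HERC5 (3.38-fold), OAS2 (3.34-fold) and IFIT3 (3.10-fold), and the guanylate-binding protein gene GBP4 (3.07-fold). OASL went from 317 ± 25.2 to 78.8 ± 1.45 CPM and IFIT1 from 451 ± 14.5 to 130 ± 14.6. The other two were HPGD, which degrades prostaglandins (3.57-fold), and the neurotrophin receptor gene NTRK2 (3.40-fold).

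**Figure D2:**
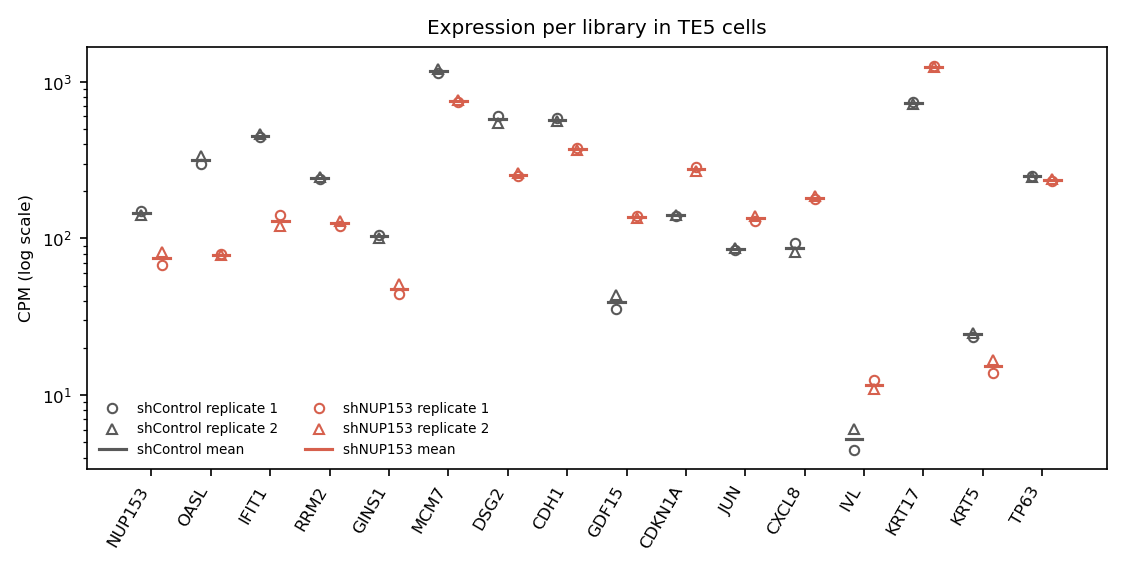
CPM on a log axis for 16 genes in each of the 4 libraries (circles, replicate 1; triangles, replicate 2; bars, group means of 2 libraries). For NUP153, OASL, IFIT1 and GDF15 the shNUP153 libraries lie apart from both shControl libraries, while TP63 differs little (248 against 235 CPM).

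Type I interferon response genes fell as a group. Of 41 measured members, 39 fell and 0 rose, the same count when adjusted over the list alone, with a median log2 fold change of −0.99 (camera adjusted p = 1.9e-136, and adjusted p = 0.273 with an estimated correlation). IFITM2 (0.848 ± 0.180 to 0.544 ± 0.00574 CPM, log2 fold change −0.65) and IRF7 (0.777 ± 0.0151 to 0.803 ± 0.0634 CPM, 0.05) did not pass the test. RSAD2, which codes for the antiviral protein viperin, fell by 1.60 on the log2 scale and overlaps CMPK2 by 14 bp on the opposite strand. In the antigen presentation list, 9 of 20 fell and 2 rose (11 and 2 adjusted over the list alone; median −0.18, adjusted p = 0.0126, and adjusted p = 0.551 with an estimated correlation). The peptidase gene ERAP2 (−0.55), the peptide transporter gene TAP1 (−0.40), TAPBP (−0.27) and the immunoproteasome gene PSMB8 (−0.30) fell, and HLA-B (0.15) was among those that rose. Without shControl replicate 2 the antigen presentation list's adjusted p was 0.124, and the call for HLA-B was lost without shControl replicate 1 or either shNUP153 library (adjusted p = 0.0786 to 0.261). Without a variance trend HLA-B (adjusted p = 0.251), TAPBP (0.0624) and PSMB8 (0.0682) did not pass, and fry gave the list an adjusted p of 0.128.

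Genes of DNA replication and S phase fell as well, 38 of 40 (39 adjusted over the list alone), with a median of −0.46 (adjusted p = 2.06e-34, and adjusted p = 0.273 with an estimated correlation). GINS1, a subunit of the replicative helicase complex, fell 2.16-fold (103 ± 3.54 to 47.9 ± 4.98 CPM), the ribonucleotide reductase subunit gene RRM2 1.95-fold, the licensing factor gene CDC6 1.62-fold and the helicase gene MCM7 1.54-fold. E2F1 (−0.12) and CCNE2 (−0.06) did not pass, though E2F1 did without shControl replicate 1 (−0.21, adjusted p = 0.0016) and with GC and length offsets (−0.17, adjusted p = 0.0051). In the mitosis and G2/M list 32 of 40 fell and 0 rose (35 adjusted over the list alone; median −0.26, adjusted p = 7.42e-11, and adjusted p = 0.376 with an estimated correlation), among them the cytokinesis gene RACGAP1 (1.86-fold lower), KIF20A (1.42-fold), PRC1 (1.38-fold) and ANLN (1.33-fold).

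For p53 targets, 11 of 27 rose and 5 fell (12 and 5 adjusted over the list alone; median 0.15, adjusted p = 6.23e-05, and adjusted p = 0.275 with an estimated correlation). CDKN1A rose 1.96-fold, from 140 ± 1.44 to 276 ± 10.4 CPM, and GADD45A 1.57-fold, next to GDF15. CCNG1 (1.45-fold lower), DDB2 (1.45-fold), RRM2B (1.26-fold), FDXR (1.24-fold) and BAX (1.11-fold), which are p53 targets too, fell. The call for BAX was lost without shControl replicate 2 (adjusted p = 0.149) and without shNUP153 replicate 1 (0.528), and that for FDXR without shNUP153 replicate 2 (0.0593). BAX also missed the threshold with quantile (0.141) and total-count scaling (0.23), DESeq2 (0.121), no variance trend (0.251) and a mean of 5 CPM or more (0.0664).

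Immediate early and AP-1 genes rose in 24 of 29 cases and fell in 0 (25 adjusted over the list alone; median 0.49, adjusted p = 8.8e-20, and adjusted p = 0.273 with an estimated correlation). The phosphatase gene DUSP5 rose 2.24-fold, IER3 1.71-fold, KLF6 1.70-fold and JUN 1.57-fold (85.6 ± 2.05 to 134 ± 6.19 CPM). FOS rose by 1.43 on the log2 scale. KLF4 (0.05), EGR1 (0.10), SPRY2 (0.13), KLF2 (0.13) and EGR3 (1.36, adjusted p = 0.0628) did not pass the test. EGR3, at 0.263 ± 0.266 CPM in shControl, passed without shControl replicate 1 (3.02, adjusted p = 0.0011), and with a pseudocount of 0.1, a replicate block, total-count scaling or GC and length offsets (adjusted p = 0.04124 to 0.04928).

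The list of NF-kB, cytokine and chemokine genes moved mostly upward, with 22 of 34 rising and 7 falling (23 and 7 adjusted over the list alone; median 0.49, adjusted p = 5.77e-08, and adjusted p = 0.273 with an estimated correlation). CXCL8 rose 2.08-fold (87.0 ± 8.15 to 181 ± 5.90 CPM), IL1A 1.99-fold and the lipocalin gene LCN2 1.96-fold. CCL5 fell 2.68-fold, CXCL10 2.66-fold, CXCL11 2.56-fold and the metalloproteinase gene MMP9 2.85-fold. MMP9 had only 21 and 30 counts in shControl and 9 and 9 in shNUP153. CCL5, CXCL10 and CXCL11 are known to be interferon-inducible. TSLP (0.08), ICAM1 (0.09), NFKBIE (0.11), MMP10 (0.27) and SAA2 (0.89, adjusted p = 0.0543) did not pass. ICAM1 passed with total-count scaling (0.16, adjusted p = 0.0427). SAA2 passed without shControl replicate 2 (1.21, adjusted p = 0.0375) and under 7 other alternatives (adjusted p = 0.03215 to 0.04739). The call for MMP9 was lost without shNUP153 replicate 1 (adjusted p = 0.0867) and without shNUP153 replicate 2 (0.0578).

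Keratinocyte differentiation genes rose, 18 of 27 measured against 1 that fell, DMKN (1.15-fold; adjusted p = 0.15 without shNUP153 replicate 2, 0.0611 with total-count scaling and 0.108 without a variance trend), with 20 and 2 when adjusted over the list alone (median 0.69, adjusted p = 4.1e-09, and adjusted p = 0.273 with an estimated correlation). IVL rose 2.19-fold (5.27 ± 1.14 to 11.6 ± 1.09 CPM), SCEL 1.94-fold, the desmosomal cadherin gene DSC2 1.61-fold and the periplakin gene PPL 1.42-fold. A further 26 genes of that list were too low to test. Basal squamous and p63-linked genes went both ways, 11 rising and 14 falling of 41 (11 and 15 adjusted over the list alone; median −0.07, adjusted p = 0.172). With no filter on low counts that list passed downward (median −0.08, adjusted p = 0.008), as it did with fry (0.0391). KRT17 rose 1.70-fold and the laminin gene LAMB3 1.49-fold, while the cadherin gene FAT2 fell 1.54-fold and KRT5 1.60-fold (24.4 ± 1.01 to 15.3 ± 2.13 CPM). Among squamous regulators, SOX2 fell by 0.34 (SE 0.07, edgeR adjusted p = 0.00013), KLF5 rose by 0.23 (SE 0.06, adjusted p = 0.0022; 0.224 without shNUP153 replicate 2 and 0.169 without a variance trend), and TP63 was −0.08 (SE 0.05, adjusted p = 0.192).

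Markers of columnar and intestinal epithelium rose in 6 of 17 cases and fell in 2, MUC1 and MUC5AC (for MUC5AC adjusted p = 0.115 without shControl replicate 2, 0.15 without shNUP153 replicate 2 and 0.111 with DESeq2). The counts were 6 and 3 adjusted over the list alone, with a median of 0.15 (adjusted p = 0.00182, and adjusted p = 0.275 with an estimated correlation). KRT7 rose 2.26-fold, AGR2 1.67-fold and CEACAM6 3.60-fold, and reads of CEACAM6 and CEACAM5 could be shared. CEACAM6 was low, at 0.98 CPM in shControl and 3.48 in shNUP153. A further 13 genes of the columnar and intestinal list were too low to test. Among them CDX1, REG4 and TFF3 had 0 counts in all libraries and HNF4A had 1 to 5. Epithelial junction genes split, with 12 of 31 rising and 10 falling (13 and 10 adjusted over the list alone; median 0.03, adjusted p = 0.759). The desmoglein gene DSG2 fell 2.25-fold (574 ± 46.1 to 255 ± 8.64 CPM), EPCAM 2.02-fold and the E-cadherin gene CDH1 1.54-fold, whereas the tight junction genes CLDN4 (1.80-fold) and OCLN (0.90 on the log2 scale) rose. Mesenchymal and EMT genes fell in 11 of 29 cases and rose in 4 (the same counts adjusted over the list alone; median −0.17, adjusted p = 0.0151, and adjusted p = 0.365 with an estimated correlation). LOXL2 fell 1.86-fold, TNC 1.78-fold and the N-cadherin gene CDH2 1.63-fold, while TPM1, COL1A1 and SNAI1 were among those that rose. The calls for TPM1 (adjusted p = 0.162 and 0.281) and COL1A1 (0.1824 and 0.1625) were lost without shControl replicate 2 and without shNUP153 replicate 1. That of COL1A1 was also lost without shNUP153 replicate 2 (0.106). With DESeq2 and without a variance trend TPM1 (0.062 and 0.164) and COL1A1 (0.13 and 0.0752) did not pass, nor did COL1A1 with no filter on low counts (0.0589).

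Of 32 nucleoporin genes, NUP153 among them, 15 fell and 3 rose, POM121C, AHCTF1 and NUP50 (17 and 3 adjusted over the list alone; median −0.14, adjusted p = 0.000274, and adjusted p = 0.365 with an estimated correlation). NUP88 fell 1.51-fold, NUP160 1.46-fold, NUP188 1.33-fold and NUP98 1.17-fold. NUP50, which binds NUP153, rose by 0.18 (SE 0.05, adjusted p = 0.00909). Without shControl replicate 2 or either shNUP153 library, the calls for NUP50 (adjusted p = 0.0668 to 0.179), POM121C (0.132 to 0.329) and AHCTF1 (0.0864 to 0.173) were lost. Without a variance trend these 3 (adjusted p = 0.167, 0.216 and 0.201) and NUP98 (0.0753) did not pass, nor did POM121C with DESeq2 (0.114) or no filter on low counts (0.106). TPR, another nuclear basket protein, was at 0.02 (SE 0.05, adjusted p = 0.836). Transport receptor and mRNA export genes fell in 16 of 35 cases and rose in 4, THOC2, NXF1, DDX39B and KPNA4 (17 and 5 adjusted over the list alone; median −0.11, adjusted p = 0.038, and adjusted p = 0.314 with an estimated correlation). XPO7 and IPO5 each fell 1.32-fold, CSE1L 1.28-fold and RANBP1 1.26-fold. The transport list's call was lost under quantile (adjusted p = 0.387) and total-count scaling (0.157), with a mean of 5 CPM or more (0.19), with GC and length offsets (0.0965), and without shControl replicate 1 (0.06577) or shNUP153 replicate 1 (0.0855). That of THOC2 was lost without shControl replicate 2 or either shNUP153 library (adjusted p = 0.078 to 0.263) and with DESeq2 (0.0653). Without a variance trend THOC2 (0.197), NXF1 (0.0608) and DDX39B (0.0619) did not pass. Lamina and chromatin architecture genes fell in 11 and rose in 6 of 33 (11 and 7 adjusted over the list alone; median −0.03, adjusted p = 0.0278, and adjusted p = 0.402 with an estimated correlation), and the median turned to 0.02 under quantile scaling, 0.04 under total-count scaling and 0.003 with a mean of 5 CPM or more, none of which left the list past its threshold, nor did leaving out shControl replicate 1 (adjusted p = 0.0747). The lamina list also missed the threshold with limma at each pseudocount and without a variance trend (adjusted p = 0.0795 to 0.0911). BANF1 fell 1.79-fold (419 ± 8.81 to 234 ± 15.7 CPM), the lamin gene LMNB1 1.5-fold, the cohesin gene SMC1A 1.43-fold and SYNE2 1.37-fold.

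In the lists of genes for making proteins and RNA, members past edgeR's test mostly fell, and the list medians were small. Abundant genes leaned the same way. In the highest of 10 equal bins of abundance, 714 of 1682 tested genes fell and 274 rose (median −0.08). Camera compared each list with the other tested genes, not with genes of the same abundance. Whether these lists, the nucleoporin and transport lists, or the nuclear-encoded respiratory chain list below fell more than genes of like abundance was not tested. The same holds for every other list, rising or falling. Cytosolic ribosomal protein genes fell in 40 of 56 cases (43 adjusted over the list alone; median −0.17, adjusted p = 9.88e-09, and adjusted p = 0.319 with an estimated correlation), led by RPS13 (1.58-fold), RPS16 (1.25-fold), RPSA and RPL6 (1.22-fold each). MYC targets in ribosome biogenesis fell in 16 of 36 cases and rose in 1, BYSL (19 and 1 adjusted over the list alone; median −0.12, adjusted p = 0.000275, and adjusted p = 0.275 with an estimated correlation), with DDX21 1.57-fold, CAD 1.43-fold, HSPD1 1.26-fold and NPM1 1.24-fold lower. The call for BYSL was lost without shControl replicate 1 or either shNUP153 library (adjusted p = 0.156 to 0.21), with DESeq2 (0.103), without a variance trend (0.167) and with no filter on low counts (0.0765). Spliceosome and SR protein genes fell in 28 of 42 cases (29 fell and 2 rose adjusted over the list alone; median −0.17, adjusted p = 3.43e-05, and adjusted p = 0.402 with an estimated correlation), including SRSF2, EFTUD2, PRPF19 and HNRNPC at 1.23-fold to 1.29-fold lower.

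Nuclear-encoded respiratory chain genes fell in 23 of 43 cases and rose in 0 (24 fell and 2 rose adjusted over the list alone; median −0.15, adjusted p = 3.43e-05, and adjusted p = 0.3 with an estimated correlation), led by COX5B (1.44-fold), ATP5F1A (1.37-fold), UQCRC2 (1.28-fold) and ATP5PB (1.25-fold). Of 15 mitochondrially encoded transcripts, 9 rose and 1, MT-CO3, fell (9 and 1 adjusted over the list alone; median 0.11, adjusted p = 0.0404, and adjusted p = 0.646 with an estimated correlation). MT-CYB rose 1.21-fold, MT-ND1 1.19-fold and MT-ND4 1.18-fold. Mitochondrial transcripts took 5.46 ± 0.209% of counts in shControl and 6.18 ± 0.582% in shNUP153 (SD, n = 2), and the mitochondrially encoded list's adjusted p was 0.622 without shNUP153 replicate 2 and 0.127 without shControl replicate 1. It was 0.0814 with robust fitting, 0.0995 with DESeq2 and 0.38 with fry. Without a variance trend MT-CYB, MT-ND1, MT-ND4 and MT-CO3 did not pass (adjusted p = 0.116 to 0.162), nor did MT-CYB (0.0631) and MT-ND4 (0.131) with DESeq2. MT-CO3 was at 0 under quantile scaling, and MT-ND4 lost its call there (adjusted p = 0.35) and without shNUP153 replicate 2 (0.06778).

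In lipid metabolism, cholesterol genes fell in 14 of 25 cases and rose in 4, among them SC5D, MSMO1 and TM7SF2 (15 and 4 adjusted over the list alone; median −0.19, adjusted p = 0.0011, and adjusted p = 0.365 with an estimated correlation). FDPS fell 1.40-fold and HMGCS1 1.36-fold. The calls for SC5D (adjusted p = 0.0673, without shNUP153 replicate 1) and MSMO1 (0.0653, without shNUP153 replicate 2) were lost with 1 library left out, and both without a variance trend (0.0611 and 0.0583). Fatty acid synthesis genes fell in 11 of 23 cases and rose in 0 (11 adjusted over the list alone; median −0.17, adjusted p = 0.00286, and adjusted p = 0.275 with an estimated correlation), with SCD 1.40-fold, ACACA 1.32-fold, FASN 1.25-fold and FADS1 1.23-fold lower. NRF2 targets, the oxidative stress response, rose in 17 of 33 cases and fell in 4, TKT, PIR, AKR1B1 and ABCC1 (18 and 6 adjusted over the list alone; median 0.31, adjusted p = 3.23e-07, and adjusted p = 0.314 with an estimated correlation). The cystine transporter gene SLC7A11 rose 1.61-fold, TXNRD1 1.58-fold and the ferritin genes FTH1 and FTL 1.41-fold each, and HMOX1 rose by 2.14 on the log2 scale from 0.807 ± 0.134 CPM. FTH1 overlaps BEST1 on the opposite strand by 1267 bp. The calls for PIR (adjusted p = 0.196), AKR1B1 (0.246) and ABCC1 (0.102) were lost without shNUP153 replicate 1. Those for AKR1B1 (0.0788) and ABCC1 (0.172) were lost without shNUP153 replicate 2, and AKR1B1 (0.172) without shControl replicate 2. With total-count scaling PIR (0.0873), AKR1B1 (0.131) and ABCC1 (0.167) did not pass, and without a variance trend they did not either (0.125, 0.182 and 0.157). AKR1B1 (0.108) and ABCC1 (0.0772) missed the threshold with quantile scaling, and AKR1B1 (0.068) with DESeq2.

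Several lists were not past the camera threshold although single members changed. The unfolded protein response and ATF4 list had 16 of 35 rising and 9 falling (16 and 9 adjusted over the list alone, and adjusted p = 0.116), with the chaperone genes HSP90B1 (1.44-fold) and CALR (1.37-fold) and the folate enzyme gene MTHFD2 (1.42-fold) lower. That list passed upward with quantile (adjusted p = 0.016) and total-count scaling (0.0375). Of 22 heat shock genes, 8 fell and 2 rose, HSPB1 and HSPA6 (8 and 2 adjusted over the list alone, and adjusted p = 0.112), with DNAJB1 1.44-fold, HSPA8 1.29-fold and HSP90AA1 1.27-fold lower. The heat shock list passed downward without shNUP153 replicate 2 (adjusted p = 0.0383), where HSPA6 did not (0.0513), with no filter on low counts (0.0058) and with DESeq2 (0.0229). YAP and TEAD targets counted 10 rising and 4 falling of 27 (10 and 5 adjusted over the list alone, and adjusted p = 0.151), and passed upward with quantile scaling (adjusted p = 0.0387). ANKRD1 rose 2.16-fold, TGFB2 1.82-fold and RND3 1.64-fold, and AXL (1.99-fold), NT5E, TEAD1 and AJUBA fell, AJUBA's call being lost without shNUP153 replicate 1 (adjusted p = 0.0606) or shNUP153 replicate 2 (0.105), with quantile (0.208) and total-count scaling (0.0812) and without a variance trend (0.144). For hypoxia and glycolysis, 8 of 32 rose and 13 fell (9 and 14 adjusted over the list alone, and adjusted p = 0.186), the median (−0.03, and 0.03 with total-count scaling) and the mean (0.03) differing in sign. The hypoxia list passed downward with no filter on low counts (adjusted p = 0.0335), with DESeq2 (0.0233) and with fry (0.0376). The glycolytic enzyme genes LDHA (1.49-fold), GAPDH (1.38-fold) and ENO1 (1.32-fold) fell and VEGFA rose 1.60-fold. Notch pathway genes rose in 6 and fell in 7 of 24 cases (6 and 8 adjusted over the list alone, and adjusted p = 0.8), NRARP rising 1.52-fold and JAG1 1.32-fold while JAG2 fell 1.46-fold and MAML1 1.29-fold. The median of the Notch list (−0.03, and 0.04 with total-count scaling) and its mean (0.0021) differ in sign. Lysosome and autophagy genes rose in 9 and fell in 8 of 30 (9 and 8 adjusted over the list alone, and adjusted p = 0.214), with ULK1 (1.67-fold), MAP1LC3B (1.54-fold) and SQSTM1 (1.37-fold) higher and CTSH 1.44-fold lower. Among 44 HOX and homeobox genes, 6 fell and 3 rose, HOXD10, HOXA3 and HOXD9 (6 and 2 adjusted over the list alone, and adjusted p = 0.82), with HOXA13 1.46-fold and HOXC13 1.36-fold lower. HOXD9 (adjusted p = 0.286, without shNUP153 replicate 2), HOXA3 (0.0816 and 0.184, without shControl replicate 1 and shNUP153 replicate 1) and HOXD10 (0.12 to 0.3035, without shControl replicate 2 or either shNUP153 library) lost their calls. With DESeq2 and without a variance trend HOXD9 (0.0503 and 0.12), HOXA3 (0.0855 and 0.0689) and HOXD10 (0.146 and 0.138) did not pass, nor did HOXD10 with no filter on low counts (0.126) or a replicate block (0.0544).

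Marker genes of other cell types were mostly near 0. Of 18 leukocyte markers, 13 were too low to test, and of the 5 tested ITGAM passed the test (4.96 ± 0.122 to 6.48 ± 0.105 CPM, adjusted p = 0.0477) but not without any 1 of the libraries (0.08518 to 0.1848) or under 6 other alternatives (0.0522 to 0.203), while LAPTM5 (−0.07), CD14 (−0.17) and CD8A (0.26) did not (0 of 5 adjusted over the list alone, and adjusted p = 0.795; median −0.07 and mean 0.06). Of 7 endothelial markers tested, CDH5 (2.16-fold) and VWF rose (2 adjusted over the list alone). The endothelial list's adjusted p was 0.205 (median −0.08 and mean 0.12), and the list passed upward with fry (0.0372). ERG (−0.64) and ESAM (0.29) did not pass. VWF's call was lost without shControl replicate 1 (adjusted p = 0.268) or either shNUP153 library (0.325 and 0.0754), with quantile scaling (0.0781), with DESeq2 (0.191) and without a variance trend (0.0862). Among 8 neural markers, SYP (0.852 ± 0.121 to 2.10 ± 0.0749 CPM) and CHGB (0.368 ± 0.0102 to 1.24 ± 0.15 CPM) rose (2 adjusted over the list alone). The neural list's adjusted p was 0.172, and the list passed upward with fry (0.0376). SYT1 (0.24) and NEFL (0.33) did not pass. SYT1 did without shControl replicate 1 (0.31, adjusted p = 0.0353), and with a mean of 5 CPM or more, total-count scaling or GC and length offsets (adjusted p = 0.0178 to 0.0329). Of 6 fibroblast markers tested, PDPN (1.99-fold lower), COL5A1 (1.59-fold) and FBLN1 (1.28-fold) fell and COL1A1 rose (3 and 1 adjusted over the list alone; median −0.26, adjusted p = 0.0011, and adjusted p = 0.275 with an estimated correlation). Of those 6, 4 also stand in another list.

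**Figure D3:**
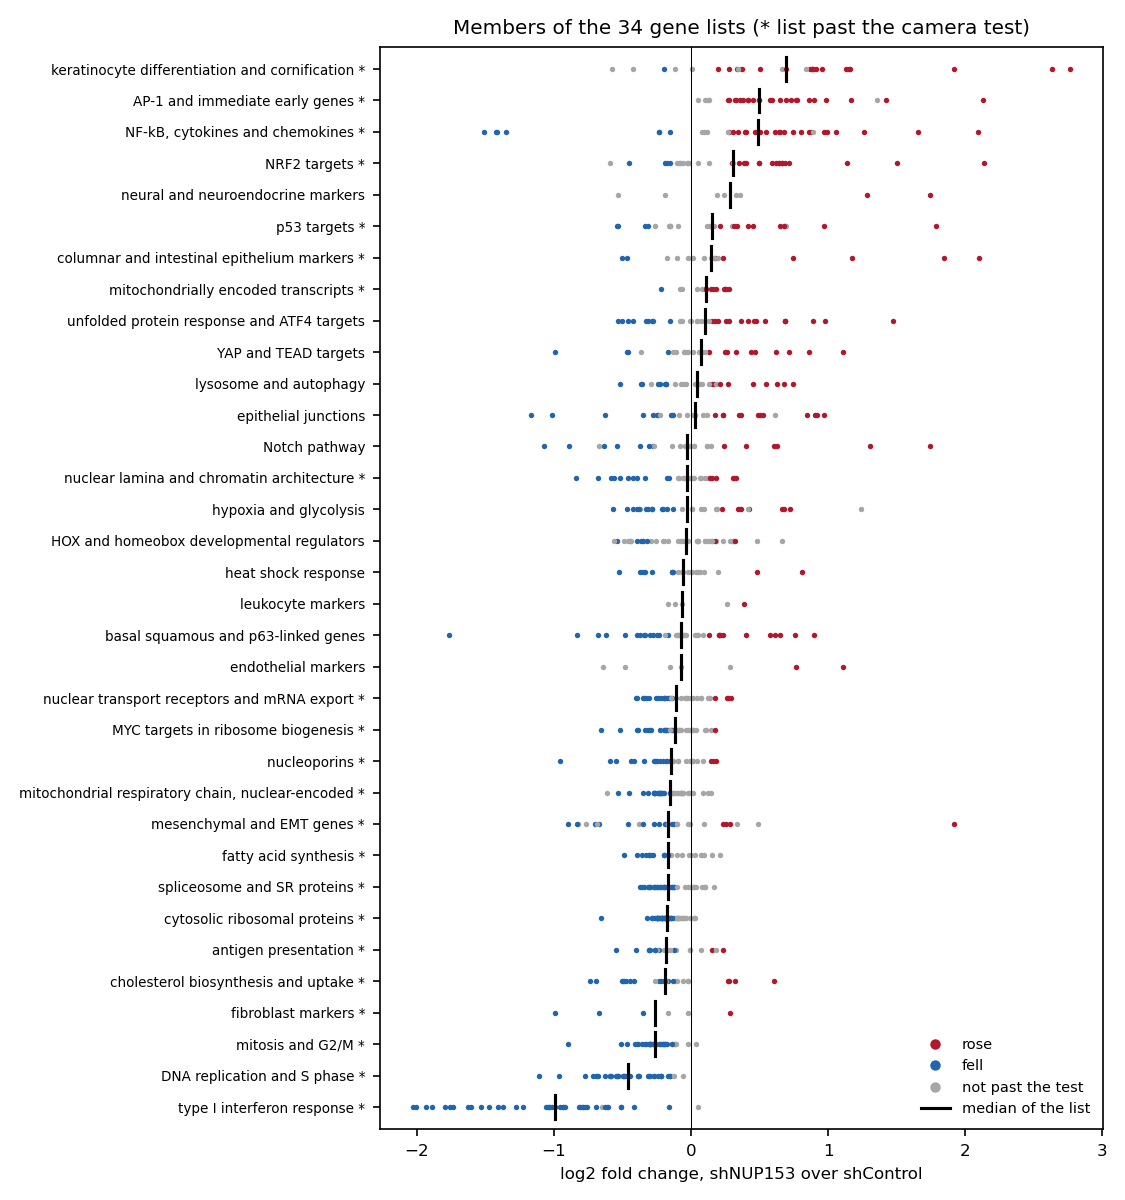
Log2 fold change (shNUP153 over shControl) of each measured member of the 34 lists, 1 point per gene, red where it rose, blue where it fell and grey where it did not pass edgeR's test, with black bars at list medians and an asterisk where camera passed. The interferon list lies lowest (median −0.99) and keratinocyte differentiation highest (0.69).

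Camera with the preset correlation called 22 of 34 lists, 7 higher and 15 lower. With an estimated correlation 0 lists passed (smallest adjusted p 0.273), with 5 at an unadjusted p under 0.05. With 2 residual degrees of freedom that version could pass few lists. The AP-1 list's estimated correlation was −0.009, below the preset 0.01, yet its camera p rose from 7.76e-21 to 0.00877. The lost calls alone therefore do not decide whether correlation between genes explains the lists. Estimates for some lists lay well above the preset, at 0.439 for mitosis and G2/M, 0.407 for antigen presentation and 0.726 for mitochondrially encoded transcripts. For such lists the camera p-values at the preset may be too small. How much of their loss came from correlation and how much from few degrees of freedom was not separated. Fry gave 24 lists in 1 direction and 32 with members changing either way. Its null is that no member changes, so with 32.4% of tested genes changed it says little about any list in particular.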

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

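Of the alternatives, limma on log2(CPM + 1), total-count scaling, GC and length offsets and the bias-adjusted method were chosen after seeing the data. NUP153 kept its direction and its call under all 18 alternatives run for it (−1.0968 to −0.825). Other named genes gave 3988 values with the same direction and call, 150 no longer past the threshold, 20 newly past it and 24 of the opposite sign or at 0. For the lists, 617 tests kept their direction and call, 43 were no longer past the threshold, 13 newly passed and 4 turned in direction. Where a library was left out, the lone library of its group is assumed to vary like the other group.

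Without a variance trend 2704 genes changed, 1329 higher and 1375 lower. DESeq2 called 3556, 1442 of them higher, and gave no adjusted p for 3261 genes, 336 of which edgeR had called. An absolute log2 fold change of 1 or more left 523 genes, 376 higher and 147 lower. With 1 library left out, 3027 to 5274 genes changed, 1312 to 2423 higher and 1715 to 2851 lower, and the lowest counts came without shNUP153 replicate 1 (3027) and replicate 2 (3300). The fewer samples and the narrower threshold account for part of these differences by construction, and the cause of the others was not tested. With an estimated correlation 0 lists passed, 0 higher and 0 lower, where 2 residual degrees of freedom let few lists pass. A replicate block changed 5465 genes (2530 higher, 2935 lower) and kept 5375 of the 5448 calls. The difference between replicates 2 and 1 in shNUP153 correlated at −0.0153 across genes with that in shControl, and with 2 pairs only the numbers were not taken to pair the libraries.

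The cause of these changes of sign or direction was not tested. TSLP was −0.1812 with a pseudocount of 0.1, −0.1092 under quantile normalization, −0.0268 without trend and on log2(CPM + 1), and −0.0415 with the replicate block. Under quantile normalization MT-CO3 was 0, TP63 0.0129, IRF7 −0.0534, KLF2 −0.0276 and the leukocyte list's median −0.07, with its test turned downward. IRF7 was −0.012 with GC and length offsets and CCNE2 was 0.0036 with total-count scaling. With DESeq2 the test of the epithelial junction list (median 0.0282) turned downward. With each library left out in turn, TSLP ranged from −1.2299 to 0.7217, CD14 from −0.929 to 0.3567, LAPTM5 from −0.2257 to 0.0717, KLF2 from −0.2549 to 0.4199, IRF7 from −0.0351 to 0.1235, ESAM from −0.0115 to 0.6182, TPR from −0.0653 to 0.103, SPRY2 from −0.0168 to 0.265, NFKBIE from −0.0386 to 0.2576 and MMP10 from −0.0072 to 0.5145. The junction list's median ranged from 0.0036 to 0.0816 and the HOX list's from −0.0406 to 0.0405, the test of each turning without shControl replicate 2. Medians of lists also changed sign where the direction of the test did not. The median of the heat shock list was 0.0172 under quantile and 0.0033 under total-count scaling, that of the HOX list 0.0296 under total-count scaling and that of the Notch list 0.0172 with a mean of 5 CPM or more. Without shNUP153 replicate 1 the endothelial list's median was 0.041, and the leukocyte list's was 0.0236 to 0.3281 with each library left out in turn. The lamina, hypoxia and Notch medians that changed sign under a scaling stand with those lists. Depth limits genes near the filter, and 39840 genes were not tested.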

Other observations

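The family, gene type and abundance summaries, the genes named here and the tests of a genomic DNA background and of nuclear RNA were chosen after the values behind them were seen.

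Families of genes sharing a symbol stem were compared by camera, 185 stems with 10 or more tested genes. With the preset correlation 15 passed, and 0 with an estimated correlation (smallest adjusted p = 0.922). The latter rests on 2 residual degrees of freedom and could pass few stems. Histone genes rose in 11 of 32 cases and fell in 1, HIST2H2AC (median 0.31, adjusted p = 0.00362). HIST2H2AC had only 19 and 32 counts in shControl and 9 and 9 in shNUP153. The call for HIST2H2AC was lost without shControl replicate 2 (adjusted p = 0.067) or either shNUP153 library (0.0928 and 0.0627). Among those that rose were HIST1H2AC (1.61-fold), HIST1H1C (1.51-fold) and HIST1H2BK (1.41-fold), and reads of near-identical histone genes may not be separable (median 0.18 under quantile scaling). Claudin genes rose in 5 of 11 cases (median 0.49, adjusted p = 0.000727), and zinc finger genes in 96 of 424, with 16 falling (median 0.14, adjusted p = 0.0185), such as ZNF432 (log2 fold change 1.00) and ZNF121 (1.48-fold). Under quantile scaling the medians of the claudin and zinc finger genes were 0.27 and 0.09. PARP genes fell in 8 of 12 cases (median −0.41, adjusted p = 1.23e-05), such as PARP12, while PARP6 rose 1.49-fold. Among those that fell, PARP9 (−1.03) and PARP14 (−0.79) also stand in the type I interferon list. GALNT genes, which start O-glycosylation, fell in 8 of 13 (median −0.24, adjusted p = 0.0353), GALNT10 by 1.32-fold. The directions of these medians were the same under relative log expression, total-count and quantile scaling. Stems were not compared with genes of the same abundance.

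Within the unfolded protein response and ATF4 list, single members went both ways. DDIT3 rose 1.97-fold, CHAC1 1.86-fold, TRIB3 1.46-fold and ASNS 1.39-fold, as did NUPR1 (2.79-fold). NUPR1 had only 11 and 10 counts in shControl and 29 and 31 in shNUP153. Its call was lost without shNUP153 replicate 2 (log2 fold change 1.36). DDIT3, at 4.65 CPM in shControl and 9.07 in shNUP153, overlaps MARS on the opposite strand by 355 bp. MARS measured 103 CPM in shControl and 114 in shNUP153, so reads counted for DDIT3 may include some of MARS. The ATF4 targets MTHFD2 (log2 fold change −0.51) and SHMT2 (−0.31) fell, and PSPH (−0.08) and PHGDH (0.04) did not pass. The endoplasmic reticulum chaperone and folding genes PDIA4 (1.34-fold), MANF (1.25-fold), PDIA6 (1.22-fold), HYOU1 (1.21-fold) and HSPA5 (1.11-fold) fell, HSPA5 losing its call with quantile (adjusted p = 0.15) and total-count scaling (0.0703). Without a variance trend the adjusted p was 0.15 for HSPA5, 0.055 for HYOU1 and 0.0522 for PDIA6. In the same list DNAJB9 (0.46) and HERPUD1 (0.42) rose.

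The fall of the type I interferon list was the largest of any list in median. Across 3 other scalings its median was at most −0.8957 (spread 0.0802), and −0.964 with GC and length offsets, which argues against scaling, GC content and length as the whole cause. Transcripts of the interferons themselves were scarce: IFNB1 had 7 and 10 counts in shControl and 5 and 5 in shNUP153, and IFNL1 fell 2.05-fold from 29 and 59 counts to 15 and 28, a call lost without shControl replicate 2 (adjusted p = 0.314) or shNUP153 replicate 1 (0.339) and without a variance trend (0.147). A response of the control cells to their own vector cannot be told apart from a fall on NUP153 loss, since 0 libraries of TE5 cells with no vector were analysed here.

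In 10 equal bins of abundance, low-abundance genes lay higher in shNUP153. Spearman's rho between log2 fold change and abundance across genes was −0.20, with medians of 0.17 in the lowest bin and −0.08 in the highest. Quantile scaling, which equalises the distributions by construction, gave 0.02 for rho and decides nothing. Genomic DNA is argued against by the reads of 835 olfactory receptor genes, whose excess would shift the 3364 genes of the lowest 2 bins by 0.0169 against 0.1613 observed, and GC content and length by a rho of −0.1815 after their removal. Whether more unspliced or nuclear RNA contributes stays open. MALAT1 rose 1.66-fold and NEAT1 1.65-fold, both retained in the nucleus, but 2 genes picked after their values were seen decide nothing. KCNQ1OT1, looked up with them, was too low to test (5 and 6 counts in shControl, 3 and 2 in shNUP153). The 137 sense-intronic genes lay at −0.0531 (SE 0.0271) from coding genes of the same abundance. That value met the bound set against this explanation, and the reading was changed to open after it was seen, because the matched coding genes would carry the same rise.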
